A study of Vitis vinifera with 12 samples.

How the data were processed

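Leaf RNA of 12 grapevine libraries, 3 at each of 25, 35, 40 and 45 °C, was compared. Per the labels' protocols, mRNA was enriched, fragmented to about 300 nt and sequenced with a strand-specific kit as 150-nt read pairs. Plants were acclimated for 2 days at 70% humidity and 800 μmol of light per square metre and second, with nights at 18 °C. Per the submitters' processing notes, CASAVA, FastQC 0.11.3, Trimmomatic 0.33 and RSEM 1.2.19 were used. The aligner and the genome build are not given in the sources used here, and coordinates are those of the deposited tables, counted from 1.

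The files hold 30 full tables, 1 for each of 5 event types and 6 comparisons, and 60 subsets of them, not analysed here. Per the file headers, the tables have the layout of rMATS with junction counts only. In each table the authors deposited inclusion and skipping junction counts as lists of 3 whole numbers per group, inclusion levels, p-values and FDR values. The deposited counts of the 25 °C libraries were the same in every table that holds an event. Deposited inclusion levels differed from recomputed ones by at most 0.0005, and the deposited FDR was the Benjamini-Hochberg adjustment of the deposited p-value. Because each cell holds a list, the unit was recorded as other. The lists were split into counts per library for the fits below, and count tools for gene tables were not run. The lists name no replicate, so libraries are called A, B and C within a group and none was paired.

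Inclusion level was the inclusion count over its form length, divided by the sum of that value for both forms. An event was tested with a mean of at least 10 junction counts per library and at least 6 counts of each form over the 6 libraries. A quasi-binomial logistic model with a group term was fitted per event in R 4.3.3. Its Pearson dispersion was moderated across the events of a table with squeezeVar of limma 3.58.1, with a trend on the log mean count and a floor of 1. An F test gave p-values, adjusted by Benjamini-Hochberg within each table, and events with adjusted p under 0.05 were called.

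The number of calls depends on the prior degrees of freedom that limma estimates, which set how strongly dispersions are shared. For retained introns and skipped exons these were unlimited in 25 against 35 °C retained introns and in 40 against 45 °C skipped exons, and between 8.12 and 1026 elsewhere. They fell to between 1.41 and 3.66 with no minimum on the mean count and at least 1 count of each form. Counts of calls from different comparisons are therefore not on the same scale. As a description without a model, chosen after these values were seen, the share of events whose 3 libraries of a group all lie above the other 3 is given in the closing section; chance gives 10%.

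On simulated data with known changes, 28% of retained introns with a change in share of 0.1 were recovered for 25 against 35 °C, and 82% with a change of 0.4. For 25 against 45 °C the values were 6% and 58% for retained introns and 34% and 88% for skipped exons. Among the simulated calls, between 0.935% and 6.25% were unchanged events. The counts were drawn with the model's own moderated dispersions, so the simulation cannot test that moderation. These values are therefore not a share of false calls in the real data.

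Levels per library used events that passed the minimum in all 3 control comparisons, with an exact permutation test of the between-group variance. Shares of calls in a direction were tested with an exact binomial test on 1 event per gene. Intervals on shares are exact 95% intervals and cover counting error only.

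Gene names and descriptions came from the deposited tables. For some entries the assembled locus spans a neighbouring gene, which is stated for the genes concerned. The 12 gene lists were fixed as words before the data were examined, to be matched in a reference table that proved to have no descriptions, so they were matched in the descriptions of the files. The words were applied as written, with symbols matched at the start of a word and scarecrow-like genes left out of the SR list. A version with wider spellings was run first and its result seen; it is kept as an alternative. Fisher's exact test compared genes with a called event with other tested genes, adjusted over 36 tests.

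Named events followed a rule fixed before the data were examined. For each control comparison it took called events with non-overlapping libraries and a mean of at least 20 counts. From these came the 4 largest rises and 2 largest falls of retained introns, the 3 largest falls and the largest rise of skipped exons, and the largest change of each alternative site type. The 2 called members with the smallest p of each of lists 1 to 8 were added. Comparisons between heated groups gave 2 retained introns, 1 skipped exon and 1 event of another type.

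Alternatives were other count minimums, a minimum change, a stricter threshold, the deposited FDR, limma on log2 ratios with 0.5 added to counts, no floor, a joint fit of the event types, a dispersion shared by the 4 groups, 1 event per gene, and leaving out each library; for levels per library, the median over events and counts pooled over events. Python 3.11.15 with scipy 1.17.1 was used for the exact and permutation tests, the last with 100000 resamples.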

Results

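Splicing was measured in leaves of potted grapevine (Vitis vinifera, cultivar 'Jingxiangyu'). Plants were kept at 25 °C or moved to 35, 40 or 45 °C for 2 h at midday, and leaves were frozen at the end of the treatment. Each of the 4 temperatures had 3 libraries and each library came from 3 plants, so the 12 libraries were separate biological samples. The deposited tables gave, for every library, the reads across junctions that include or skip a piece of sequence. The 5 kinds of event were retained introns, skipped exons, alternative 3' splice sites, alternative 5' splice sites and mutually exclusive exons. The inclusion level is the length-corrected percentage of transcripts that keep the piece. Over the tested events of a comparison, a library held between 640933 and 1014831 junction counts. Between 5509 and 6277 events were tested per comparison. Events of a gene often share exons, so genes were counted as well.

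The first question was how far the leaf's mean inclusion level moved with temperature. Retained introns were kept more often in the hotter groups, and alternative exons were kept less often. The mean inclusion level of 1961 retained introns was 26.8% ± 1.57 (SD, n = 3) at 25 °C, 27.3% ± 0.669 at 35 °C, 29.5% ± 0.856 at 40 °C and 31.9% ± 0.615 at 45 °C. That of 922 skipped exons was 64.9% ± 0.607 at 25 °C, 63.2% ± 0.589 at 35 °C, 61.5% ± 0.643 at 40 °C and 60.8% ± 1.69 at 45 °C. The 4 groups differed for retained introns (two-sided exact permutation test over 15400 partitions, p = 0.000519) and for skipped exons (exact permutation p = 0.00149). They were not separated for alternative 3' sites (exact permutation p = 0.176), alternative 5' sites (exact permutation p = 0.223) or mutually exclusive exons (exact permutation p = 0.0614). A comparison of 3 libraries with 3 cannot give an exact p below 0.1, which retained introns reached at 40 and 45 °C and skipped exons at 35, 40 and 45 °C, each against 25 °C. Pooling the counts over events in place of averaging events gave a skipped-exon difference of -0.656 points between 45 and 25 °C (exact permutation p = 0.726 over the 4 groups) in place of -4.10, and one of 17.6 for retained introns in place of 5.05. The median over events gave -8.95 points for skipped exons.

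**Figure D1:**
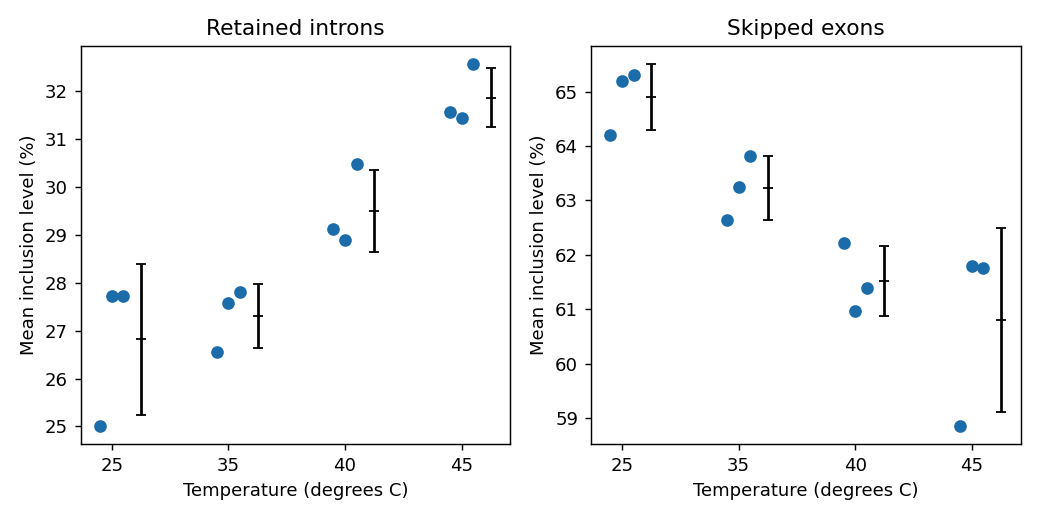
Mean inclusion level (%) of retained introns and skipped exons against temperature (°C). Each point is 1 library, and the bar beside each set of 3 points is their mean with its SD; retained introns average 26.8% at 25 °C and 31.9% at 45 °C.

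At 35 °C the leaves already differed from the 25 °C control in the splicing of individual genes, with more exons skipped. Among 76 called skipped exons, 55 were included less at 35 °C. RSZ32, a serine/arginine-rich splicing factor with zinc finger motifs, had the largest change among the called alternative 3' sites that were named by rule. Use of its 151-nt extension (chromosome 8, positions 13908912 to 13909062, plus strand) rose from 11.5% ± 7.16 to 56.5% ± 2.61 (SD, n = 3, adjusted p = 1.31e-10). SCL30A, a related splicing factor, included its 158-nt exon (chromosome 6, 843474 to 843631) in 9.17% ± 6.28 of transcripts at 25 °C and in 1.35% ± 1.32 at 35 °C (adjusted p = 6.27e-05).

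Introns moved both ways at 35 °C. The intron of a RING/U-box protein gene (VIT_05s0051g00750, chromosome 5, 11701432 to 11701511) rose from 1.13% ± 1.96 to 45.7% ± 5.43, at a mean of 22.2 counts per library. Its assembled locus also spans VIT_05s0051g00730, so the gene is uncertain. CGL1, an N-acetylglucosaminyltransferase of glycoprotein synthesis, rose from 5.81% ± 2.15 to 39.8% ± 7.59. GTE8 fell from 71.9% ± 19.03 to 33.0% ± 3.27. ATCBL3, a calcineurin B-like calcium sensor, fell from 88.9% ± 19.2 to 45.8% ± 12.0 at a mean of 18.3 counts. A splicing factor gene with a PWI domain (VIT_01s0026g00140) fell from 99.5% ± 0.837 to 86.0% ± 9.82. Among exons, AtSS2 fell from 84.3% ± 12.5 to 38.3% ± 15.2, and a WD40 repeat gene (VIT_09s0002g05790) rose from 4.27% ± 3.99 to 37.9% ± 14.2. TEJ, a poly(ADP-ribose) glycohydrolase, used its 63-nt alternative 5' extension in 16.3% ± 15.1 and 63.4% ± 2.12 of transcripts (adjusted p = 0.00371), at a mean of 20.8 counts.

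In all, 172 of 5881 events in 136 genes were called between 25 and 35 °C, 69 higher and 103 lower at 35 °C. The test was a quasi-binomial model with dispersions moderated by limma and an adjusted p under 0.05. Skipped-exon calls were lower at 35 °C in 45 of 61 genes (exact two-sided binomial p = 0.000264), and retained-intron calls were higher in 25 of 47 genes (exact binomial p = 0.771). Here and below these p-values are descriptions, because all genes were measured in the same libraries. The test against an even share also ignores starting levels. A fully included exon cannot rise and a fully removed intron cannot fall, so part of a direction may come from that. limma on log2 count ratios called 2 events and none of the 15 named ones, and leaving out library A, B or C left 86, 36 or 111 events for the 25 °C group and 15, 23 or 45 for the 35 °C group. Only VIT_05s0051g00750 among the named events stayed called without each library, and the skipped-exon share became 0% of 2 calls without the 25 °C library A, 33.3% of 3 without the 25 °C library B or the 35 °C library C, and 50% of 6 without the 35 °C library B, while without the 35 °C library A the model called 0 skipped exons (253 at unadjusted p under 0.05); of the skipped exons at unadjusted p under 0.05, 70.3% to 77.5% were lower without each library.

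At 40 °C several introns went from nearly always removed to nearly always kept. CES101, a lectin receptor-like kinase, retained its 107-nt intron (chromosome 7, 13364941 to 13365047, plus strand) in 2.15% ± 2.15 of transcripts at 25 °C and in 95.8% ± 4.21 at 40 °C (SD, n = 3, adjusted p = 1.78e-06). A GTP-binding HflX gene (VIT_00s0734g00020) rose from 1.56% ± 1.87 to 87.8% ± 1.68. An FCA gamma-related gene (VIT_07s0005g01730), from the family of a flowering time regulator, rose from 0.703% ± 0.67 to 70.1% ± 6.10 at a 3721-nt intron. An aldolase-type gene (VIT_09s0002g00820) rose from 2.06% ± 3.57 to 93.1% ± 4.05. The last pair lie in assembled loci that also span a neighbouring gene.

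Splicing regulators were again among the changed genes. RSZ32 used its 3' extension at 79.3% ± 8.71 (adjusted p = 1.43e-06). The PWI-domain splicing factor gene fell to 39.2% ± 11.0 at its 268-nt intron (chromosome 1, 8777553 to 8777820). SCL30A stood at 1.16% ± 0.313. The retained intron of ATX1 fell from 71.2% ± 31.2 to 14.6% ± 6.52. Exons lost included those of ATDGK3, a diacylglycerol kinase (89.7% ± 17.9 to 19.98% ± 2.25), and TGA6, a transcription factor (89.8% ± 17.7 to 27.4% ± 1.26). A WAPL-like gene (VIT_00s0370g00050) moved from 0% in all 3 libraries to 67.1% ± 2.94 at its 2526-nt alternative 5' extension. RCA, rubisco activase, kept a 91-nt intron in 34.1% ± 5.71 of transcripts at 25 °C and in 16.99% ± 1.10 at 40 °C. The clock genes PRR7, whose locus also spans a neighbour, and TOC1 fell from 99.8% ± 0.284 to 93.8% ± 1.98 and from 100% to 94.7% ± 1.72. CIPK3, a kinase that binds calcium sensors, fell from 44.6% ± 5.23 to 22.7% ± 6.91. A thioredoxin family gene (VIT_10s0597g00030) fell from 95.9% ± 4.78 to 64.1% ± 4.88 at its 80-nt exon. An RNA-binding protein gene (VIT_11s0016g03670) fell from 24.9% ± 3.43 to 6.96% ± 2.56.

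Between 25 and 40 °C, 1059 of 5934 events in 785 genes were called, 476 higher and 583 lower at 40 °C. As a description over genes that share libraries, retained-intron calls were higher in 218 of 303 genes (exact two-sided binomial p = 1.26e-14). Skipped-exon calls were lower in 309 of 368 genes (exact binomial p = 5.25e-42). The exons called lower had a median level of 99.8% at 25 °C, against 86.7% for the other tested exons. Many of them thus had little room to rise, which the binomial test does not take into account. Without the 25 °C library A or B, 528 or 425 events were called, and without the 40 °C library A, B or C, 208, 233 or 551; without A or B the model called 0 skipped exons (496 or 461 at unadjusted p under 0.05). Of the 24 named events 8 stayed called without each library, among them CES101, the HflX gene, RSZ32 and RCA, whereas SCL30A, ATX1, ATDGK3, TGA6, PRR7, TOC1, CIPK3, VIT_10s0597g00030 and VIT_11s0016g03670 each lost the call without at least 1; RCA and CIPK3 were not called by limma on log2 ratios.

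At 45 °C retained introns made up 328 of the 639 called events, and 299 of them were higher. ATHSFA2, a heat stress transcription factor, retained its 89-nt intron (chromosome 4, 921931 to 922019, minus strand) in 7.79% ± 2.98 of transcripts at 25 °C and in 89.0% ± 4.37 at 45 °C (SD, n = 3, adjusted p = 0.00014). The event had a mean of 1905 counts per library. At 40 °C it stood at 54.4% ± 25.0, which did not pass against 25 °C (adjusted p = 0.193) but passed against 35 °C (adjusted p = 0.00323), and passed against 25 °C by the FDR in the authors' deposited table (6.35e-08). HSF4 rose from 0.251% ± 0.434 to 9.22% ± 5.52. HSP98.7 moved from 0% in all 3 libraries to 13.8% ± 1.90 in a choice between mutually exclusive exons. CPN20, a chloroplast co-chaperonin, rose from 0% in all 3 libraries to 44.5% ± 3.21 (adjusted p = 0.00014). CES101 reached 99.1% ± 0.283, and a RING/U-box gene (VIT_07s0031g00230) rose from 8.51% ± 7.38 to 91.3% ± 3.68.

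Some introns were spliced out more at 45 °C. ATX1 fell to 15.7% ± 7.10, and CYP704A2, a cytochrome P450, fell from 93.3% ± 5.79 to 45.8% ± 16.3. Exon inclusion fell in ATDGK3 to 17.9% ± 17.4, in the potassium transporter gene KUP7 (its locus also spans a neighbour) from 97.8% ± 3.72 to 61.9% ± 3.52, and in CPK32, a calcium-dependent kinase, from 98.1% ± 1.19 to 83.4% ± 7.94. BLH1 had the largest rise of the named exons, from 14.7% ± 3.03 to 31.0% ± 6.31. The RNA-binding protein gene VIT_11s0016g03670 fell from 26.7% ± 3.37 to 5.85% ± 0.667 at a longer version of its exon. RSZ32 stood at 56.3% ± 22.3 and SCL30A at 0.285% ± 0.493. The alternative 3' site of TZP stood at 60.03% ± 38.6 against 5.79% ± 2.89 in the control, at a mean of only 4 counts per library at 45 °C.

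Between 25 and 45 °C, 639 of 5565 events in 471 genes were called, 356 higher and 283 lower at 45 °C. As a description over genes that share libraries, retained-intron calls were higher in 248 of 276 genes (exact two-sided binomial p = 3.27e-45). Skipped-exon calls were lower in 169 of 176 genes (exact binomial p = 2e-41). Without the 25 °C library A, B or C, 204, 229 or 353 events were called (3 skipped exons without A), and without the 45 °C library A or C, 202 or 171, with 0 skipped exons in both (266 or 358 at unadjusted p under 0.05). Of the 27 named events 7 stayed called without each library, among them CES101, ATHSFA2, CPN20 and HSP98.7, whereas HSF4, RSZ32, SCL30A, ATX1, CYP704A2, ATDGK3, KUP7, CPK32, BLH1, TZP and VIT_11s0016g03670 each lost the call without at least 1.

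**Figure D2:**
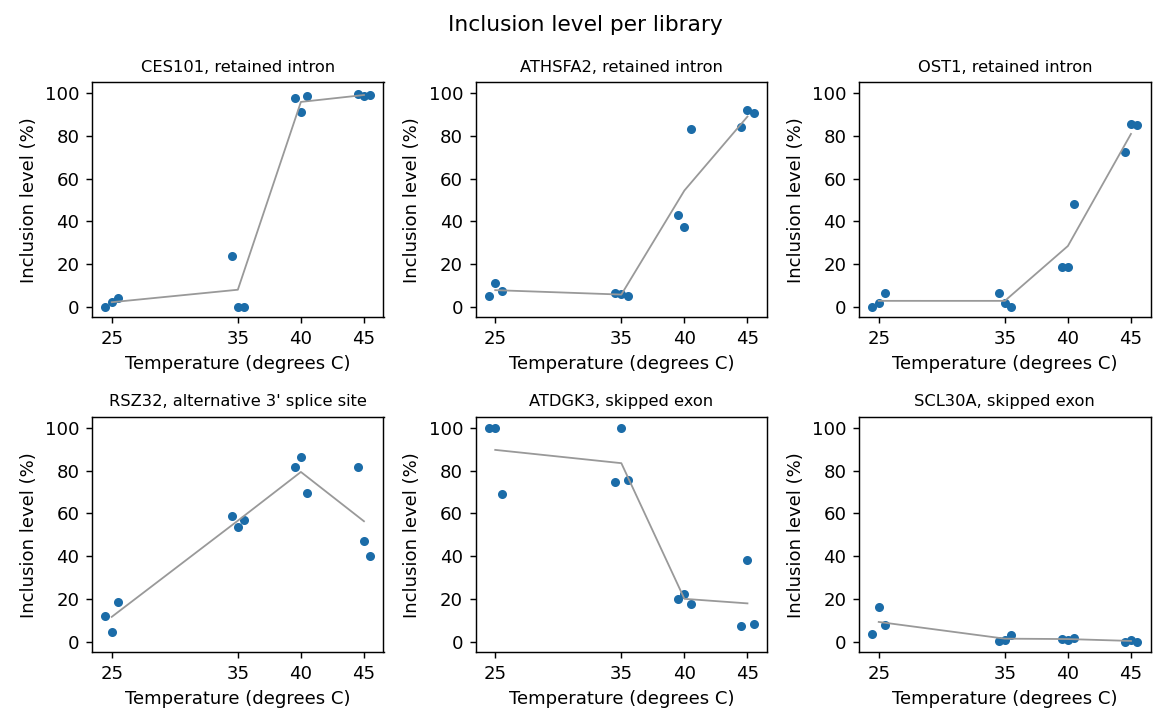
Inclusion level (%) of 6 named events against temperature (°C), with 1 point per library and a line through the group means. ATHSFA2 averages 5.72% at 35 °C and 89.0% at 45 °C, and RSZ32 averages 56.5% at 35 °C.

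The 12 gene lists were compared with the other tested genes in each control comparison, and none of the 36 tests passed after adjustment (Fisher's exact test). An unadjusted p under 0.05 was found for 3 of them. These were SR splicing factors at 35 °C (2 of 7 genes called, Fisher's exact p = 0.0303, adjusted p = 0.56), and ubiquitin and proteasome genes at 40 °C (13 of 31, Fisher's exact p = 0.0311, adjusted p = 0.56) and at 45 °C (9 of 33, Fisher's exact p = 0.0495, adjusted p = 0.594). None passed against random lists matched for depth either. Heat shock proteins and chaperones had 0 of 35 genes called at 35 °C (3 at unadjusted p under 0.05, 0 by the deposited FDR), 8 of 37 at 40 °C and 8 of 39 at 45 °C. Adjusted over the list alone, 0, 11 and 12 of their events passed. By the FDR in the authors' deposited table, 16 of the 39 were called at 45 °C, and that list passed (adjusted p = 0.00899). Heat stress transcription factors had 0 of 4, 0 of 6 and 2 of 6 genes called (0, 1 and 3 at unadjusted p under 0.05, 0, 1 and 2 by the deposited FDR), and 0, 0 and 4 events adjusted over the list alone. SR splicing factors had 3 of 6 at 40 °C and 2 of 7 at 45 °C, with 3, 5 and 2 events adjusted over the list alone. Other spliceosome and RNA-binding genes had 1 of 14, 6 of 17 and 3 of 13, with 4, 14 and 7 such events.

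The model's counts of 0 below are followed by the genes at unadjusted p under 0.05 and those called by the deposited FDR. Antioxidant genes had 0 of 24 (3 and 0), 5 of 27 and 7 of 26 genes called, with 0, 9 and 10 events adjusted over the list alone. All 9 of their called events at 40 °C were exons included less. Photosynthesis genes had 0 of 12 (3 and 1), 2 of 13 and 2 of 12, with 2, 2 and 0 events adjusted over the list alone. Clock and light receptor genes had 0 of 6 (0 and 0), 3 of 5 and 1 of 5, with 0, 4 and 2. Calcium and kinase signalling genes had 1 of 15, 3 of 16 and 2 of 14, with 1, 0 and 2. Ubiquitin and proteasome genes had 0 of 29 (8 and 1) at 35 °C, and 0, 17 and 10 events adjusted over the list alone. Ribosomal protein genes had 1 of 29, 6 of 31 and 3 of 35, with 2, 4 and 3. Hormone response genes had 0 of 14 (3 and 0), 0 of 10 (2 and 1) and 0 of 10 (3 and 2), with no event adjusted over the list alone. Epidermis and cuticle genes, which mark another cell layer of the leaf, had 1 of 3, 1 of 3 and 0 of 2 (1 and 1), with 2, 1 and 1.

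The heated groups were also compared with each other. Between 35 and 40 °C, BAM1, a beta-amylase of starch breakdown, retained a 1579-nt intron in 4.76% ± 8.25 and 93.7% ± 6.98 of transcripts (SD, n = 3, adjusted p = 0.0023), with a mean of 3.33 counts per library at 35 °C. CES101 rose from 7.98% ± 13.8 to 95.8% ± 4.21, ATDGK3 fell from 83.4% ± 14.3 to 19.98% ± 2.25, and the WAPL-like gene rose from 1.70% ± 2.40 to 67.1% ± 2.94. In this step 429 of 6277 events were called, 227 higher and 202 lower at 40 °C. Without the 35 °C library A, B or C, 108, 73 or 126 were called, and without the 40 °C library A or B, 210 or 108. Between 35 and 45 °C, 516 of 5933 events were called, 342 higher and 174 lower, and BAM1 reached 96.3% ± 1.87. TZP had 62.2% ± 33.6 at 45 °C, at a mean of 8 counts, against 4.99% ± 0.415 at 35 °C. Without the 35 °C library A, B or C, 180, 174 or 174 events were called, and without the 45 °C library A or C, 233 or 173. BAM1 between 35 and 40 °C, ATDGK3 in both comparisons and TZP between 35 and 45 °C each lost the call without at least 1 library.

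Between 40 and 45 °C, OST1, a kinase of abscisic acid signalling that closes stomata, retained its 73-nt intron (chromosome 3, 4518820 to 4518892) in 28.4% ± 16.97 and 80.9% ± 7.50 of transcripts (SD, n = 3, adjusted p = 0.0134). ATCBL3 rose from 41.9% ± 20.4 to 99.1% ± 1.52. A protein kinase gene (VIT_17s0000g01810) lost exon inclusion, from 96.5% ± 3.04 to 75.03% ± 10.5. An alternative 5' extension of a PAP/OAS1 domain gene (VIT_08s0058g01140) fell from 41.9% ± 12.8 to 9.14% ± 7.27. Of 5509 events, 112 were called, 44 higher and 68 lower at 45 °C. This count and its direction are uncertain: the FDR in the authors' deposited table called 255 of the same events, 172 higher and 83 lower at 45 °C, with 167 retained introns where the model called 9, and limma on log2 ratios called 1. By the description without a model, libraries did not overlap in 934 of the 5509 events, 551 higher and 383 lower at 45 °C. Without the 40 °C library A or B the model called 2 or 4, and without the 45 °C library A, B or C it called 32, 23 or 17. None of the 4 named events stayed called without each library.

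**Figure D3:**
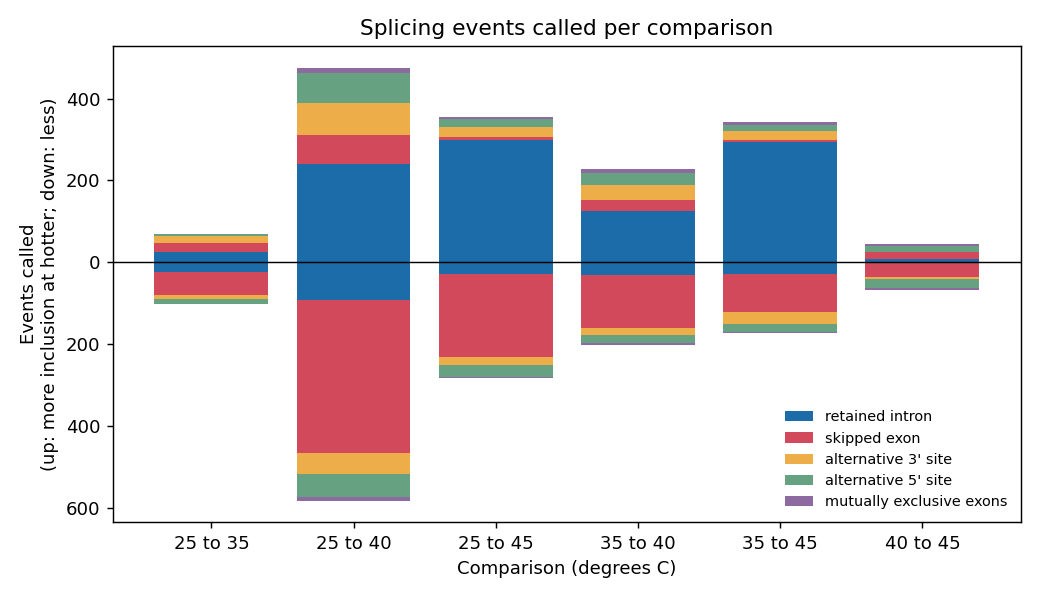
Number of events called in each comparison (°C, cooler to hotter), with bars above 0 for more inclusion and below 0 for less inclusion at the hotter temperature, coloured by event type. The 25 to 40 °C comparison has 1059 calls and the 40 to 45 °C comparison 112.

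Calls recurred across comparisons. Against the shared 25 °C libraries, 338 events were called in the same direction at 40 and 45 °C, where independent lists would share 41.8. The numbers were 121 for 35 and 40 °C (11.2 for independent lists) and 65 for 35 and 45 °C (5.81 for independent lists). Simulated unchanged groups gave 0 calls, so they set no number of shared calls to compare with. The covariances of the changes were 0.0151, 0.0101 and 0.00606, and 0.000863, 0.000506 and 0.000521 in simulated unchanged groups. The simulated values are no reference for the real ones. Those groups were drawn around the observed shares of the same control libraries, so the chance error of the controls largely cancelled. Part of each excess over independent lists may come from the shared control libraries. Among pairs without a common library, 195 events were called in the same direction between 25 and 45 °C and between 35 and 40 °C (20.1 for independent lists) and 0 in opposite directions. For 25 to 40 °C and 35 to 45 °C the numbers were 172 (38.7 for independent lists) and 9 (39.6 for independent lists). The steps from 25 to 35 °C and from 40 to 45 °C shared 1 called event in the same direction (1.47 for independent lists) and 23 in opposite directions (1.38 for independent lists). Fisher's exact test on calls shared in either direction gave p = 1.19e-105, 2.62e-34 and 5.94e-17 for these 3 pairs, and it does not test the direction. The 23 are uncertain: with limma on log2 ratios only 2 events were called between 25 and 35 °C and 1 between 40 and 45 °C, and without the 40 °C library A or B only 2 or 4 between 40 and 45 °C, too few to share 23, while 42 were shared in opposite directions and 0 in the same by the FDR in the authors' deposited table.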

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

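The shares of junction counts, the test of introns with lower retention, the tests of splits, of exons alone, of counts per event and of total depth at 45 against 25 and 40 °C were chosen after the results they bear on were seen; the other tests here were fixed before their results were seen.

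Junction counts of the deepest event of each gene, inclusion plus skipping, were expressed as a share of those of all 2650 genes. This share was higher in all 3 libraries at 45 °C than in all 3 at 25 °C for 2 of the 12 lists. Both lists differed over the 4 groups. Heat shock proteins and chaperones (31 genes) took 1.09% ± 0.450 (SD, n = 3) of the junction counts at 25 °C, 15.9% ± 1.09 at 40 °C and 15.3% ± 4.93 at 45 °C (exact permutation test over the 4 groups, p = 0.00364, adjusted p = 0.00727); 16 genes were higher and 6 lower in all 3 libraries at 45 °C than in all 3 at 25 °C. Heat stress transcription factors (4 genes) took 0.0441% ± 0.0135 and 0.973% ± 0.0719 (exact permutation test over the 4 groups, p = 6.49e-05, adjusted p = 0.000779), of which ATHSFA2 alone made 0.922%. Only genes with an event past the count minimum in all 3 control comparisons enter these shares, which are not total counts of a gene.

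Retained introns had a mean inclusion level 5.05 points higher at 45 °C than at 25 °C. A rise that leaves no intron with lower retention is argued against, since 8.84% of the called introns were lower at 45 °C (exact 95% interval 6.001 to 12.5). Some calls at an adjusted p under 0.05 may be false. Without 1 library, 87.2% to 95.8% of the called introns were higher at 45 °C, so the lower share was smaller in some of these fits. Total depth stays open: libraries at 45 °C held 0.872 times the counts of those at 25 °C over the events shared by the 4 groups, between the bounds set, but 0.981 times over the events of this comparison and 0.973 times over the introns; thinning all libraries to 418219 counts kept 96.3% of the difference, which decides nothing because thinning leaves expected shares unchanged. Counts per event stay open too, and they were lower at the typical intron. The median over 1961 introns was 40.7 counts per library at 25 °C and 22.7 at 45 °C. The 492 introns with at least 30 counts in each library differed by 3.06 points (SE 0.507), between the bounds set. Intronic sequence spread evenly over genes stays open: its test was void, because the median change in depth-scaled inclusion counts was negative both for introns with few and for those with many spliced counts (-9.43 and -1.17), and the ratio of 0.124 cannot be read. An effect of temperature itself may also account for the pattern, so the cause stays undecided.

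Fewer events were called at 45 °C (639) than at 40 °C (1059) against the control. Lower total depth is argued against, since libraries at 45 °C held 1.02 times the counts of those at 40 °C over the events shared by the 4 groups (0.953 times over the events tested between them), but counts per event stay open: with both groups thinned to equal counts at each event, 87.3% of the excess of calls at 40 °C among events tested in both comparisons (758 against 520 calls) was kept (70.2% to 102% over 20 thinnings), between the bounds set. A smaller change at 45 °C in exon and splice-site events is consistent with the data: the noise-corrected mean square change was 0.416 of that at 40 °C (bootstrap 95% interval 0.329 to 0.507; 0.418 for exons alone), although the mean exon level moved no less, by -4.10 points at 45 °C and -3.38 at 40 °C. The bootstrap resampled events as if they were independent, and not libraries, so its interval does not cover the spread between libraries. A larger spread at 45 °C stays open, with a ratio of dispersions of 1.09 that lies between the bounds set for it. Without any model, libraries did not overlap in 31.0% of events at 40 °C and 23.8% at 45 °C, where chance gives 10%.

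With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, reached its own count. The real counts and the highest of the other splits were 172 and 20 (25 against 35 °C), 1059 and 13 (25 against 40 °C), 639 and 14 (25 against 45 °C), 429 and 2 (35 against 40 °C), 516 and 12 (35 against 45 °C), and 112 and 9 (40 against 45 °C).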

How the results depend on the processing

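The wider list spellings and the count of non-overlapping libraries were chosen after seeing the data. Alternatives are named in the order 25 against 35, 25 against 40, 25 against 45, 35 against 40, 35 against 45 and 40 against 45 °C. With no minimum on the mean count and at least 1 count of each form, 1, 46, 19, 7, 24 and 0 events were called. More events entered there, for 25 against 35 °C 7237 retained introns in place of 2578. In this setting limma's prior degrees of freedom for retained introns and skipped exons were at most 3.66. Which of these changes lowered the counts was not tested. At adjusted p under 0.01 the counts were 86, 402, 230, 160, 222 and 34. Leaving out 1 library gave 15 to 111, 208 to 721, 171 to 451, 73 to 329, 173 to 425 and 2 to 151, with fewer libraries. The 4 groups with 1 dispersion gave 111, 613 and 351 against the control. That setting kept only the events shared by the 4 groups, so fewer events were tested. Whether the smaller event set or the shared dispersion lowered these counts was not tested. limma on log2 ratios gave 2 for 25 against 35 °C and 1 for 40 against 45 °C. A mean of at least 30 counts gave 340 for 35 against 45 °C and 60 for 40 against 45 °C, with fewer events tested. The authors' deposited FDR gave 255 for 40 against 45 °C; the cause was not tested. Removing the floor on the dispersion changed no count of calls.

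The share of retained-intron calls higher at 35 °C was 52% of 50 calls (25 of 47 genes, exact binomial p = 0.771). It was 49.1% with a mean of 30 counts, 46.2% with a change of at least 0.1, 50% in the joint fit and 0% of 1 call with limma. It was higher with the deposited FDR (60.3% of 73 calls), 1 dispersion for the 4 groups (64.7% of 17), 1 event per gene (59.5% of 37) and adjusted p under 0.01 (53.3% of 30). Without 1 library it ran from 36.8% to 66.7%. The share of skipped-exon calls lower at 35 °C ran from 0% to 69.2% without 1 library, with 2 to 6 calls where it was under 69.2%, and had no value without the 35 °C library A, where no skipped exon was called; of skipped exons at unadjusted p under 0.05, 70.3% to 77.5% were lower without each library. At 40 °C the leave-out ranges were 68.7% to 79.7% for retained introns and 79.9% to 84.5% for skipped exons, and at 45 °C 87.2% to 95.8% and 94.0% to 100%, the last with 3 calls without the 25 °C library A. The skipped-exon ranges leave out the 40 °C libraries A and B and the 45 °C libraries A and C. Without each of these no skipped exon was called. limma's prior degrees of freedom for skipped exons also fell in these fits, from 8.12 to 2.23 and 1.92 at 40 °C. At 45 °C they fell from 19.7 to 1.65 and 2.94. Whether the missing library or the weaker sharing of dispersions removed the exon calls was not tested. Of skipped exons at unadjusted p under 0.05 in these fits, 86.3% and 83.5% were lower at 40 °C, and 94.7% and 95.5% at 45 °C. The 45 °C level minus the control was 4.14 to 5.50 points for retained introns and -4.60 to -3.12 for skipped exons without 1 library, and 17.6 and -0.656 with counts pooled over events, and -8.95 for skipped exons with the median; the cause was not tested.

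The deposited FDR gave 1 list past the threshold in place of 0, and 0 events in place of 1 shared in direction by 25 against 35 and 40 against 45 °C; the cause was not tested. Of the named events, 1 of 15 at 35 °C, 8 of 24 at 40 °C and 7 of 27 at 45 °C stayed called in every fit without 1 library, and 15, 3 and 6 were lost with limma on log2 ratios. DESeq2 and edgeR, which are count tools for gene tables, were not run. No paired analysis was possible because the lists carry no replicate numbers.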

Other observations

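The enrichment and the per-library shares of gene lists were chosen after seeing the data; the tests of intron length, exon length and starting level were fixed before their results were seen. Genes with retained introns higher at 45 °C were enriched for the deposited term protein folding, with 10 of 26 term genes among 92 of 787 annotated genes (Fisher's exact test, odds ratio 5.18, adjusted p = 0.0225). It was the only one of 70 tests over the called introns at 40 and 45 °C and exons at 40 °C to pass. These tests were not matched for junction depth. Heat shock proteins and chaperones took a larger share of junction counts at 45 °C than at 25 °C. Over all event types, 8 of the 39 genes of that list were called at 45 °C. Random lists matched for depth averaged 5.86, and the list did not pass against them. Whether depth accounts for the protein folding enrichment was not tested. For protein phosphorylation at 40 °C, 1 of 69 genes had a higher retained intron (adjusted p = 0.0606) and 16 of 29 had a lower exon (adjusted p = 0.0748), neither past the threshold.

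The share of junction counts, over the deepest event of each gene, was lower at 45 °C than at 25 °C in other lists. Clock and light receptor genes took 0.172% ± 0.0158 (SD, n = 3) of counts at 25 °C and 0.0792% ± 0.0148 at 45 °C (exact permutation test over the 4 groups, adjusted p = 0.0026). Calcium and kinase signalling genes took 0.377% ± 0.0296 at 25 °C, 0.462% ± 0.0514 at 35 °C and 0.223% ± 0.0336 at 45 °C (exact permutation test over the 4 groups, adjusted p = 0.000779). A share falls when others rise, so these values are relative.

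Short introns are a candidate explanation for retention at 45 °C, and the data did not go that way: called introns had a median length 52 nt above the others (308 against 256 nt, permutation p = 0.177). Exons skipped more at 40 °C might be those that break the reading frame. However, 43.9% of them had a length that is a multiple of 3, against 35.9% of the others (Fisher's exact p = 0.00663). Events of a gene often share exons, and with 1 event per gene the shares were 43.5% and 36.1% (Fisher's exact p = 0.0319). The median level at 25 °C of the exons skipped more was 13.2 points above that of the others. That decides nothing, since an exon near 0 has no room to fall.

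Assembled loci without a gene name carry the prefixes T28, T35, T40 and T45 in the deposited tables. The prefix T28 stands on 368 table lines, whereas the labels give 25 °C as the control.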
